A study of Mus musculus with 20 samples.

How the data were processed

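RNA was measured in pancreatic beta cells of male mice 6 to 8 months old on a standard chow diet, per the labels. Islets were isolated and beta cells were collected by fluorescence-activated sorting on a tomato reporter switched on by Cre recombinase under the rat insulin promoter. There were 5 libraries of each of 4 genotypes. WT is wild type, IKO lacks Foxo1, HKO lacks Hnf4a and DKO lacks both. Libraries were strand-directional, poly-A selected and sequenced as short paired-end reads on an Illumina HiSeq, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

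The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to depth) with 20 library columns, and 0 columns of other samples. The submitters' processing notes name STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 1.14.1 and the mouse build mm10, without their roles or order. The gene annotation, any read filters and whether counting used strand are not given in the sources used here. Reads of overlapping genes and of near-identical copies can therefore have been split or assigned to a partner, which makes single members of such families uncertain (Ins1 and Ins2, Try4 and Try5, Hspa1a and Hspa1b, Eif3j1 and Eif3j2, Jmjd7 and Pla2g4b, H2-K1 and H2-D1).

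The table listed 27179 entries. Of these, 847 were named NA, 27 carried a date in place of a gene name and 26305 had a usable name. Entries named NA held 0.0810 to 0.204% of reads per library and date-named entries 0.160 to 0.186%, and both were left out of the tests. FPKM values were turned back into reads by searching, per entry, for the value of 1 read in each library, with the relative depths taken from entries at up to 0.3 FPKM. Whole reads (within 0.02 reads) came out for all 21006 entries above 0 in any library, 100% of them, and gene lengths were whole within 0.05 bases for 99.99%. On simulated FPKM values of 3919 genes in 4 groups, 98.6% of genes were recovered exactly. Library totals ranged from 22.6 to 34.7 M reads with a median of 27.8 M. Since the deposited unit was FPKM, no count test was used for the main results. The recovered reads served for depth, for the comparison of replicates and for 1 added alternative, limma's voom on the reads.

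Replicates were compared before averaging by a chi-square statistic per degree of freedom on the recovered reads, over genes with at least 20 reads in the 2 libraries together. Sampling noise alone gives 1. Within every group, replicates 1 and 2 and replicates 4 and 5 lay far closer to each other (8 pairs, 1.44 to 3.08, median 1.69) than all other pairs (32 pairs, 6.05 to 21.5, median 10.9). The close pairs differed by more than sampling noise, which repeat preparations of 1 sample can do too, so this does not show that they are separate samples. The fit fixed in advance takes 5 libraries per group, and the number of genes passing in each comparison is given again with close pairs averaged into 1 sample and with the close pairs treated as correlated (limma's duplicateCorrelation, consensus correlation 0.81). Replicates 1 and 2, replicate 3, and replicates 4 and 5 are called library sets. No label names a batch or says that libraries came from separate animals. All p-values therefore measure only the spread between these libraries, which may be technical.

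Genes with a mean of at least 0.5 FPKM over the 20 libraries (12455 genes) were tested on log2(FPKM + 0.5) with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend) in R 4.3.3. All 20 libraries shared 1 estimate of the spread. The 6 comparisons were IKO, HKO and DKO against WT, DKO against HKO, DKO against IKO, and the interaction, which is DKO minus HKO less IKO minus WT. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low FPKM. Levels are means of FPKM with their SD over 5 libraries. Foxo1 and Hnf4a were also tested by exact two-sided permutation of 5 against 5 libraries, whose smallest p is 0.00794. This and every other exact permutation of libraries below counts close pairs as separate libraries, which can make its p too small.

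The comparisons, the limma fit, the rule for named genes, 25 gene lists and most other settings were fixed before the data were examined. The lists included beta cell transcription factors, insulin production and granule genes, glucose sensing and exocytosis, FoxO targets, genes disallowed in beta cells, dedifferentiation and progenitor genes, markers of alpha cells, of delta, PP and epsilon cells, of acinar cells, of ductal cells, of endothelial cells, of stellate cells and fibroblasts and of immune cells, endoplasmic reticulum (ER) stress, fatty acid oxidation, glycolysis, oxidative phosphorylation, cholesterol synthesis, fatty acid and triglyceride synthesis, cell cycle, immediate early genes of dissociation stress, lactogen response, interferon response and MHC class I, and the mitochondrial genome. Each list was tested in each comparison with camera at a preset correlation of 0.01 and adjusted over all 150 tests. Camera with an estimated correlation and fry, which asks only whether a list's own genes move one way on balance, were the alternatives. Members were also adjusted over the list alone. The results of 1 list, and some genes that the rule below names, are not reported here.

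Named genes were Foxo1 and Hnf4a, and per comparison the 8 highest and 8 lowest log2 fold changes among genes that passed, had a mean of at least 2 FPKM in the higher group and showed no overlap between the libraries of the 2 groups. For the interaction only the adjusted p and FPKM conditions applied. Gene models known by a Gm number, a Rik name or a clone name were left out. Per list, up to 4 passing members with the smallest p were named and, where fewer than 2 passed, the 2 members of highest mean FPKM. Names outside this rule are said to be chosen after their values were seen.

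The fit was tested on simulated data for HKO against WT with 12455 genes, 200 of them changed, in 20 draws. With independent libraries it recovered 78.1% of 1.5-fold, 94.7% of 2-fold and 98.9% of 4-fold changes, with 5.24% of its calls false. With close pairs as correlated as the real ones, 60.6% of its calls were false, and a median of 145 genes passed where nothing was changed. On the same simulated data, averaging recovered 55.4%, 87.5% and 97.7% with 5.27% false calls, and the correlated fit recovered 64.3%, 90.4% and 97.7% with 5.21% false calls. These simulations drew each gene independently and gave each group its own set effects. In the real libraries genes varied together and set deviations were shared across genotypes, so these rates may not hold there. In a separate simulation for the same comparison, with independent libraries and lists of random genes, camera called the 1 shifted list and 0 of the other lists. It held no close pairs and no lists whose members vary together, so it does not show how often camera calls falsely in the real data.

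For the sharing of controls between comparisons, unchanged groups were simulated 100 times from the residuals, keeping library sets together. The HKO libraries were split in 10 ways and the WT libraries in 20 ways to lessen the sharing of libraries between linked comparisons, which remains in part where a split parts a close pair. Settings tried as alternatives, fixed in advance, were pseudocounts of 0.1 and 1, no filter and a filter of 2 FPKM, scaling to equal medians, quantile normalization, only the groups compared, limma's robust fit, array weights, a fold of at least 1.5, the replicate number as a block, and leaving out each of the 20 libraries. Added after seeing the data were averaging of the close pairs without and with the library set as a term, the correlated fit, voom, the acinar transcript level as a covariate, and leaving out the 3 libraries highest in acinar transcripts (HKO replicates 4 and 5 and DKO replicate 3). Gene positions came from GENCODE vM21 on GRCm38, where 12077 of the genes tested matched 1 position each (97.0%). Reads were recovered and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.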

Results

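Transcript levels were measured in 20 libraries of sorted mouse beta cells, 5 each from WT, IKO (without Foxo1), HKO (without Hnf4a) and DKO (without both) animals. Foxo1 and Hnf4a are transcription factors that control metabolic genes, and the title of the series describes their networks as opposing each other. The comparisons ask what each factor's loss does alone, what the loss of both does, and whether loss of Foxo1 offsets the loss of Hnf4a. Library totals were 26.8 to 34.7 M (mega) reads in WT, 22.6 to 29.4 M in IKO, 22.8 to 31.6 M in HKO and 23.1 to 34.2 M in DKO. Ins1 and Ins2, the insulin genes, took 14.9 to 22.3% of all reads, and between 16781 and 17695 genes were above 0 per library. Transcripts of the mitochondrial genome took 1.53 to 4.63% of reads and the ribosomal RNA precursor Rn45s 0.245 to 1.47%. Libraries also differed within groups. Replicates 1 and 2 of each genotype lay close to each other in their reads, as did replicates 4 and 5. Across genotypes, deviations from the group means had a median correlation of 0.30 between libraries numbered 1 or 2, 0.37 between those numbered 4 or 5 and −0.33 between these sets (across genes, which are not independent replicates). Between libraries numbered 3 it was 0.0131 (−0.386 to 0.254), so replicate 3 of different genotypes shared no such pattern. A value given for replicate 3 therefore sets single libraries against each other, without a shared set.

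Foxo1 transcript was low in every library of both genotypes that carry its deletion. It measured 6.64 ± 1.48 FPKM in WT (SD, n = 5) and 1.11 ± 0.46 FPKM in IKO, which is 16.7% of WT (log2 fold change −2.18, SE 0.21, limma adjusted p = 3.42e-05, exact p = 0.00794). In HKO it measured 5.97 ± 1.84 FPKM and in DKO 1.40 ± 0.26 FPKM, 23.5% of HKO (log2 −1.73, limma adjusted p = 0.00142, exact p = 0.00794). With close pairs averaged, the adjusted p of Foxo1 was 0.0778 in IKO against WT and 0.447 in DKO against HKO, and with close pairs correlated 0.000385 and 0.00768. Hnf4a measured 5.56 ± 0.86 FPKM in WT, 5.39 ± 1.02 in IKO, 3.82 ± 0.35 in HKO and 3.99 ± 0.34 in DKO (n = 5 each). HKO stood at 68.8% of WT with no overlap between libraries (log2 −0.48, SE 0.12, exact p = 0.00794). Hnf4a did not pass over all genes there (limma adjusted p = 0.0630). The adjusted p was 0.0198 without WT replicate 3, 0.0229 without IKO replicate 5 and up to 0.179 without another library. With close pairs averaged or correlated, its adjusted p in HKO against WT was 0.999995 and 0.917. DKO stood at 74.0% of IKO (log2 −0.38, exact p = 0.0317, limma adjusted p = 0.161). The adjusted p was 0.0394 without IKO replicate 5 and up to 0.308 without another library. Hnf4a also did not pass in DKO against IKO with close pairs averaged or correlated. Against WT the DKO level was 71.7% (log2 −0.43, exact p = 0.0159, limma adjusted p = 0.0928). The adjusted p was 0.0321 without WT replicate 3, 0.0406 without IKO replicate 5 and up to 0.273 without another library. With close pairs averaged and correlated it was 0.999877 and 0.999875. Gene-level FPKM counts reads of exons outside the floxed part too, so the remaining Hnf4a signal does not by itself measure how complete the deletion was. Foxo1 lies on chromosome 3 (52268336 to 52353221, plus strand) and Hnf4a on chromosome 2 (163506808 to 163572910, plus strand) in GRCm38.

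**Figure D1:**
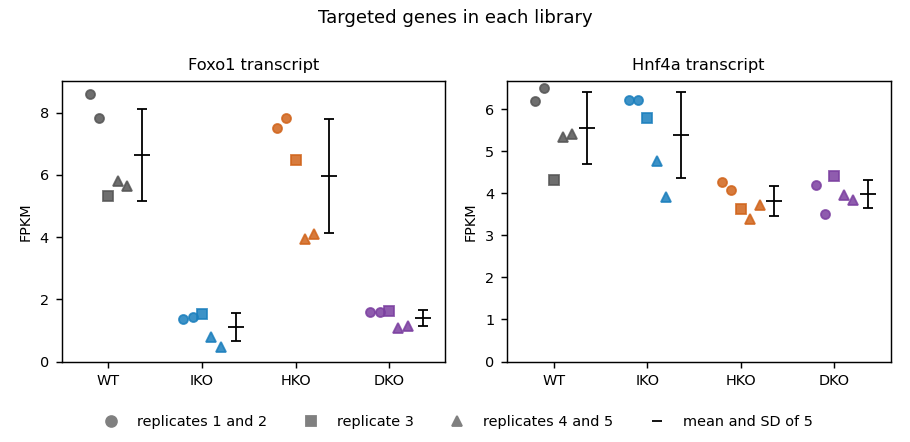
FPKM of Foxo1 (left) and Hnf4a (right) in each of the 20 libraries by genotype, with circles for replicates 1 and 2, squares for replicate 3, triangles for replicates 4 and 5, and black bars for the mean ± SD of 5. Foxo1 means were 6.64 FPKM in WT, 1.11 in IKO and 1.40 in DKO, and Hnf4a means were 5.56 FPKM in WT and 3.82 in HKO.

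Loss of Foxo1 alone changed few single genes. Foxo1 itself fell, and 2 genes rose in IKO against WT. Myo7a, an unconventional myosin, went from 0.154 ± 0.174 to 1.31 ± 0.372 FPKM (log2 1.48, SE 0.24, limma adjusted p = 0.0209, n = 5), and Tmem74b, a transmembrane protein, from 0.257 ± 0.117 to 0.986 ± 0.308 FPKM (log2 0.96, SE 0.16, adjusted p = 0.0209). Both were named after their values were seen, since their levels lay under the FPKM limit for named genes. In all, 3 of 12455 genes passed, 536 had an unadjusted p under 0.05, and 66.7% of the calls were higher, against 33.3% after scaling to equal medians and 50% after quantile normalization. Averaging of close pairs left 0 genes by limma (122 at an unadjusted p under 0.05) and the correlated fit left 1, Foxo1. Leaving out IKO replicate 3 gave 29 genes, HKO replicate 3 gave 6, WT replicate 3 gave 5, and WT replicates 1, 2, 4 or 5 or IKO replicate 4 gave 1. Simulated unchanged groups gave a median of 0 genes, up to 187 at the upper end of their range, and 3 or more in 14 of 100 draws. Myo7a lost its call without any 1 of WT replicates 1, 2, 4 or 5 or IKO replicates 4 or 5 (adjusted p up to 0.110). Tmem74b lost its call without WT replicates 1, 2, 4 or 5 or IKO replicates 1, 2 or 4 (up to 0.114).

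Several fixed gene lists shifted in IKO against WT while none of their members passed over all genes. Glycolysis genes stood higher, with a median log2 fold change of 0.28 over 17 measured members, 15 of them above 0 (camera adjusted p = 1.87e-06, adjusted p = 0.402 with an estimated correlation). Ldha, lactate dehydrogenase, measured 4.57 ± 0.876 FPKM in WT and 23.0 ± 18.3 in IKO, and Tpi1, triosephosphate isomerase, 138 ± 6.78 and 211 ± 72.2 FPKM. Within library sets the glycolysis median was 0.73 for replicates 1 and 2, −0.22 for replicate 3 and 0.31 for replicates 4 and 5. Interferon response and MHC class I genes had a median of −0.35 over 18 members (adjusted p = 1.89e-08, adjusted p = 0.592 with an estimated correlation), with set medians of 0.25, −0.39 and −0.94. Cholesterol synthesis genes had a median of −0.17 over 20 members (adjusted p = 9.03e-06, adjusted p = 0.402 with an estimated correlation), and 1 was lower when adjusted over the list alone, with set medians of −0.14, 0.02 and −0.20. Other lists called lower were oxidative phosphorylation (median −0.04, adjusted p = 0.00282, 0.592 with an estimated correlation), acinar cell markers (−0.44, 0.00477, 0.755 with an estimated correlation) and immune cell markers (−0.21, 0.0110, 0.631 with an estimated correlation). Leaving out 1 library ended the calls of acinar markers (WT replicates 2 or 3 or IKO replicates 4 or 5, adjusted p up to 0.480), oxidative phosphorylation (WT replicate 3 or IKO replicate 2, up to 0.130) and immune markers (WT replicate 3 or IKO replicate 1, up to 0.211). FoxO targets as a list had a median of 0.04 (adjusted p = 0.230), and 0 of its 22 measured members passed in limma, over all genes or adjusted over the list alone.

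Among the named genes the largest fall in HKO against WT was that of Anks4b, a scaffold protein of microvilli, from 13.8 ± 1.75 FPKM in WT to 3.93 ± 0.669 in HKO (log2 −1.69, SE 0.15, limma adjusted p = 3.0e-06, n = 5). Dio1, a thyroid hormone deiodinase, fell from 20.6 ± 3.39 to 7.66 ± 1.52 FPKM (log2 −1.37, adjusted p = 9.12e-05), and Tmprss4, a transmembrane serine protease, from 16.7 ± 3 to 6.63 ± 1.21 FPKM (log2 −1.27, adjusted p = 0.000290). Hpgds, a prostaglandin D synthase, had a log2 fold change of −1.5, Nnat (neuronatin, which aids insulin maturation) −1.17, the chemokine Ccl28 −1.05 and Gatm, an enzyme of creatine synthesis, −1.04. Among the named genes the largest rise was that of Sparcl1, a secreted matrix protein, from 0.513 ± 0.249 to 3.89 ± 0.969 FPKM (log2 2.12, SE 0.19, adjusted p = 3.47e-06). Npy, the gene of neuropeptide Y, rose from 11.2 ± 3.75 to 33.6 ± 13 FPKM (log2 1.52, adjusted p = 0.00172), Arhgap36 from 2.52 ± 0.381 to 6.08 ± 1.45 FPKM (log2 1.10, adjusted p = 0.000199), and the adhesion gene Ceacam10 from 0.873 ± 0.268 to 2.04 ± 0.59 FPKM (log2 0.88, adjusted p = 0.00736).

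In HKO against WT 98 genes passed, 22 higher and 76 lower, with 880 at an unadjusted p under 0.05. The count was 26 with close pairs correlated and 5 with close pairs averaged, all of them among the 98. Simulated unchanged groups, which keep the closeness of the library pairs, gave a median of 0 genes, up to 113 at the upper end of their range, and 98 or more in 3 of 100 draws. In another simulation, with genes drawn independently, close pairs as correlated as the real ones and nothing changed, a median of 145 genes and up to 208 passed. Sparcl1, Anks4b, Sel1l3 and the beta-carotene cleaving enzyme Bco1 passed in all 3 fits. Dio1, Tmprss4, Hpgds, Nnat, Ccl28, Npy, Arhgap36 and Vil1 passed in the correlated but not in the averaged fit (averaged adjusted p 0.0680 to 0.589). Gatm, Ceacam10, Pigr, Sprr1a, Pklr, Fdps, Gpx2 and Myo7a passed in neither (correlated adjusted p 0.0507 to 0.688). Without the 3 libraries highest in acinar transcripts 112 genes passed, 64 of them shared. Among other named genes, Pigr (the polymeric immunoglobulin receptor, log2 −1.03) and Sprr1a (a cornified envelope protein, 1.52) lost their calls when 1 library was left out, with adjusted p up to 0.0993 and 0.104. For Pigr these were WT replicates 2 to 5 and HKO replicates 1 and 2, and for Sprr1a WT replicates 1 to 4 and HKO replicates 4 and 5.

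Vil1, which encodes the microvillus protein villin, was lower in HKO than in WT (22.1 ± 4.14 to 11.9 ± 0.291 FPKM, log2 −0.84, limma adjusted p = 0.00916). So was Pklr, the liver-type pyruvate kinase gene (5.60 ± 0.77 to 3.62 ± 0.358 FPKM, log2 −0.56, adjusted p = 0.0300). The call of Pklr was lost without any 1 of WT replicates 1, 2, 4 or 5 or HKO replicates 1, 2, 4 or 5 (adjusted p up to 0.0979). Cholesterol synthesis genes had a median of −0.14, with 0 of 20 above 0 (camera adjusted p = 3.75e-06, adjusted p = 0.383 with an estimated correlation), 1 lower over all genes (Fdps, farnesyl diphosphate synthase, log2 −0.35) and 2 adjusted over the list alone. The call of Fdps was lost without any 1 WT library or any 1 of HKO replicates 2 to 5 (adjusted p up to 0.0855). Immediate early genes of dissociation stress had a median of 0.29 with 16 of 16 above 0 (adjusted p = 1.61e-08, adjusted p = 0.245 with an estimated correlation), and 0.17, −0.08 and 0.60 within replicates 1 and 2, replicate 3 and replicates 4 and 5. Egr1 and Btg2 were higher adjusted over the list alone, and the list's adjusted p was 0.241 without the 3 acinar-high libraries.

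Acinar cell markers, the digestive enzyme genes of the exocrine pancreas, stood higher in HKO against WT with a median of 2.49 and 19 of 19 members above 0 (camera adjusted p = 3.75e-28, adjusted p = 0.245 with an estimated correlation). In limma 1 of 19 passed over all genes and 19 of 19 adjusted over the list alone. Ctrb1, chymotrypsinogen, measured 46.3 ± 34.4 FPKM in WT, 38.1 ± 28.3 in IKO, 267 ± 196 in HKO and 151 ± 182 in DKO. The mean log2 level of the list was 2.5 ± 1.17 in WT, 2.06 ± 1.24 in IKO, 4.87 ± 0.95 in HKO and 3.79 ± 1.26 in DKO (n = 5). Within library sets the HKO against WT median was 0.91, 0.78 and 4.82 for replicates 1 and 2, replicate 3 and replicates 4 and 5. Other lists called in this comparison were the mitochondrial genome (median 0.50, adjusted p = 0.000332, 0.628 with an estimated correlation), fatty acid and triglyceride synthesis (−0.07, 0.0105, 0.706 with an estimated correlation) and interferon response and MHC class I (−0.18, 0.0122, 0.755 with an estimated correlation). Endothelial markers (−0.45, 0.0162, 0.706 with an estimated correlation) and glycolysis (−0.13, 0.0197, 0.706 with an estimated correlation) were called lower. A library set went the other way for fatty acid synthesis (replicate 3, 0.22), interferon response (replicates 1 and 2, 0.16) and glycolysis (replicates 4 and 5, 0.18). Leaving out 1 library ended the calls of endothelial markers (WT replicates 4 or 5 or HKO replicates 2 or 3, adjusted p up to 0.156) and glycolysis (WT replicate 3 or HKO replicates 1 to 3, up to 0.372). It also ended those of interferon response (WT replicates 3 to 5 or HKO replicates 1 to 3, up to 0.484) and fatty acid synthesis (HKO replicate 4, up to 0.0633).

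**Figure D2:**
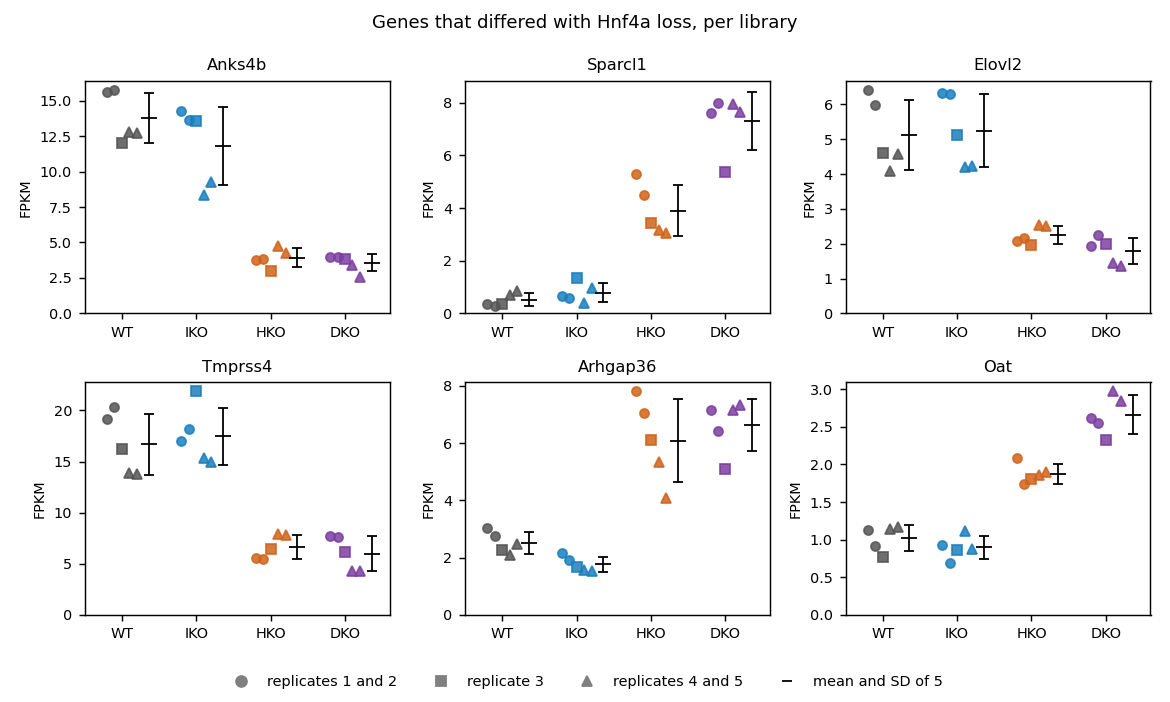
FPKM of 6 genes in each of the 20 libraries by genotype, with circles for replicates 1 and 2, squares for replicate 3, triangles for replicates 4 and 5, and black bars for the mean ± SD of 5. Anks4b, Elovl2 and Tmprss4 were lower and Sparcl1, Arhgap36 and Oat higher in HKO and DKO than in WT and IKO, with Anks4b at 13.8 FPKM in WT and 3.56 in DKO.

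In DKO against WT, 76 of the 98 genes that passed in HKO against WT also passed. Sparcl1 rose to 7.32 ± 1.10 FPKM (log2 2.97, SE 0.19, limma adjusted p = 2.86e-08, n = 5) and Anks4b fell to 3.56 ± 0.599 FPKM (log2 −1.82, SE 0.15, adjusted p = 5.83e-07). Elovl2, an elongase of polyunsaturated fatty acids, fell from 5.13 ± 1.01 to 1.79 ± 0.377 FPKM (log2 −1.30, adjusted p = 1.69e-05), and Bco1 from 3.02 ± 0.399 to 1.07 ± 0.196 FPKM (log2 −1.16, adjusted p = 5.97e-06). Oat, ornithine aminotransferase and a gene normally kept low in beta cells, rose from 1.02 ± 0.172 to 2.66 ± 0.258 FPKM (log2 1.06, adjusted p = 1.65e-06). Krt19, a keratin of duct cells, rose from 1.70 ± 0.656 to 6.12 ± 3.67 FPKM (log2 1.51, adjusted p = 0.0024), and its highest value was in DKO replicate 3, which also held the most acinar transcripts of that group. Further changes were Sprr1a (log2 2), Npy (1.51), Ceacam10 (1.25), Arhgap36 (1.24), Hpgds (−1.57), Tmprss4 (−1.43), Dio1 (−1.35) and Vil1 (−1.06).

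In DKO against WT 150 genes passed, 56 higher and 94 lower. Simulated unchanged groups gave as many in 3 of 100 draws. The other simulation with nothing changed, run for HKO against WT with genes drawn independently, gave a median of 145 and up to 208. The correlated fit gave 42 and averaging 17, all among the 150, and 17 passed in all 3 fits (5 higher, 12 lower). Krt19, Sprr1a, Npy, Hpgds and Vil1 passed in the correlated but not in the averaged fit (averaged adjusted p 0.155 to 0.291). Cldn11, Pklr, Ttr, Hgfac, Nnat and Gpx2 passed in neither (correlated adjusted p 0.102 to 0.558). Without the 3 acinar-high libraries 166 passed, 133 of them shared. Vil1, Pklr, Hgfac and Ttr were among the genes lower. The tight junction gene Cldn11 (log2 1.07) lost its call without any 1 of WT replicates 1 or 2 or DKO replicates 1, 2, 4 or 5 (adjusted p up to 0.0785), and Pklr (log2 −0.57) without WT replicates 1 or 2 or DKO replicates 4 or 5 (up to 0.0675). The calls of Ttr, the thyroxine carrier transthyretin (log2 −0.40), and of Hgfac, a serine protease (log2 −0.44), were also lost. For Ttr this was without WT or DKO replicates 1, 2, 4 or 5 (up to 0.0920). For Hgfac it was without WT replicates 2 to 5, IKO replicates 1 or 2, HKO replicates 1, 2, 4 or 5 or any 1 DKO library (up to 0.143). Acinar markers had a median of 1.33 (camera adjusted p = 8.84e-08, adjusted p = 0.706 with an estimated correlation) with 0 members passing in limma, over all genes or adjusted over the list alone. Immediate early genes had a median of 0.31 (adjusted p = 2.21e-05, adjusted p = 0.383 with an estimated correlation), with Atf3, Dusp1 and Zfp36 higher adjusted over the list alone and set medians of 0.43, −0.11 and 0.35. Glycolysis had a median of −0.19 (adjusted p = 0.00420, 0.706 with an estimated correlation, Pklr passing), genes disallowed in beta cells 0.08 (0.0482, 0.706 with an estimated correlation, Oat passing) and the mitochondrial genome 0.35 (0.0496, 0.751 with an estimated correlation, −0.07 in replicates 4 and 5). The call of the disallowed genes was lost without WT replicates 1 or 2, IKO replicates 1, 3 or 5, any 1 HKO library or DKO replicates 3 to 5 (adjusted p up to 0.202). That of the mitochondrial genome was lost without WT replicates 2, 4 or 5, IKO replicates 1 to 3, any 1 HKO library or DKO replicates 1 to 3 (up to 0.326).

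Loss of Hnf4a on a background without Foxo1, DKO against IKO, changed 52 of the 98 genes that passed in HKO against WT past the threshold. Sparcl1 rose from 0.789 ± 0.371 FPKM in IKO to 7.32 ± 1.10 in DKO (log2 2.63, limma adjusted p = 1.91e-07, n = 5). Arhgap36 rose from 1.76 ± 0.272 to 6.63 ± 0.924 (log2 1.66, adjusted p = 6.78e-07) and Oat from 0.896 ± 0.152 to 2.66 ± 0.258 (log2 1.18, adjusted p = 3.12e-07). Clip4 (log2 1.04), the calcium-binding protein gene Kcnip3 (0.87) and Olfm2 (0.99) also rose. Anks4b (log2 −1.58), Tmprss4 (−1.5), Hpgds (−1.42), Elovl2 (−1.32), Bco1 (−1.15), Dio1 (−1.09), Nnat (−1.05) and the phospholipid transporter gene Abcb4 (−1.01) fell. In all 138 genes passed, 44 higher and 94 lower, and simulated unchanged groups gave as many in 4 of 100 draws. The other simulation with nothing changed, run for HKO against WT with genes drawn independently, gave a median of 145 and up to 208. The correlated fit gave 26 and averaging 15, all among the 138, and 15 passed in all 3 fits (5 higher, 10 lower). Hpgds, Dio1 and Vil1 passed in the correlated but not in the averaged fit (averaged adjusted p 0.128 to 0.641). Kcnip3, Olfm2, Nnat, Gc, Ttr, Pfkl, Tpi1, Pgam1, Dusp1, Fos, Zfp36 and Irs2 passed in neither (correlated adjusted p 0.0697 to 0.808). Leaving out IKO replicate 3 gave 250 genes, DKO replicate 2 gave 85, IKO replicate 2 gave 87, IKO replicate 5 gave 90 and DKO replicate 4 gave 91. Without the 3 acinar-high libraries 156 passed, 118 of them shared.

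Glycolysis genes stood lower in DKO than in IKO, with a median of −0.42 (camera adjusted p = 9.4e-10, adjusted p = 0.254 with an estimated correlation), 3 lower over all genes and 13 lower and 1 higher adjusted over the list alone. Pfkl, a phosphofructokinase, measured 54.7 ± 24.4 FPKM in IKO and 23.5 ± 3.05 in DKO (log2 −1.09), against 33.1 ± 3 in WT. Tpi1 had 211 ± 72.2 and 106 ± 14.5 (log2 −0.91), while the phosphoglycerate mutase gene Pgam1 had 28.2 ± 7.45 and 17.0 ± 3.64 (log2 −0.70). Without DKO replicate 1, 2, 4 or 5 or IKO replicate 1, 2 or 4 all 3 lost their calls. Tpi1 lost it also without IKO replicate 5 or DKO replicate 3. Pgam1 lost it also without IKO replicate 5, HKO replicate 1 or 2 or any 1 WT library (limma adjusted p up to 0.0954 for Pfkl, 0.112 for Tpi1 and 0.134 for Pgam1). Within library sets the DKO against IKO median was −0.93 for replicates 1 and 2, 0.09 for replicate 3 and −0.39 for replicates 4 and 5. Vil1 (log2 −0.93), Gc (−0.52) and Ttr (−0.42) were also lower over all genes. The call of Ttr was lost without IKO replicate 5 or DKO replicate 2 or 5 (adjusted p up to 0.0609). Acinar markers had a median of 1.81 (adjusted p = 1.21e-12, 0.592 with an estimated correlation), with 0 of 19 passing over all genes in limma and 18 adjusted over the list alone. Immediate early genes had a median of 0.17 (adjusted p = 0.000975, 0.592 with an estimated correlation), with Fos, Dusp1 and Zfp36 higher over all genes and 4 adjusted over the list alone. Each of these 3 lost its call without IKO replicates 1 or 2 or DKO replicates 1 or 2. Fos lost it also without WT replicate 1, IKO replicates 4 or 5 or DKO replicates 4 or 5. Zfp36 lost it also without WT replicates 1 or 5, IKO replicate 5 or DKO replicates 3 to 5 (limma adjusted p up to 0.0772 for Dusp1, 0.112 for Fos and 0.121 for Zfp36). Cholesterol synthesis (0.18, adjusted p = 0.0104, 0.706 with an estimated correlation), interferon and MHC class I (0.24, 0.0104, 0.755 with an estimated correlation) and immune markers (0.34, 0.0277, 0.706 with an estimated correlation) were higher and ER stress genes lower (−0.07, 0.0482, 0.706 with an estimated correlation). In replicates 1 and 2 the median was −0.03 for cholesterol synthesis and −0.16 for interferon response. Leaving out 1 library ended the calls of cholesterol synthesis (DKO replicate 3, adjusted p up to 0.0853) and immune markers (IKO replicate 1 or DKO replicate 3, up to 0.169). It also ended those of interferon response (DKO replicates 3 to 5, up to 0.0934) and ER stress (WT replicates 3 or 4, IKO replicates 1, 2 or 5, HKO replicate 2 or DKO replicate 3, up to 0.528).

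**Figure D3:**
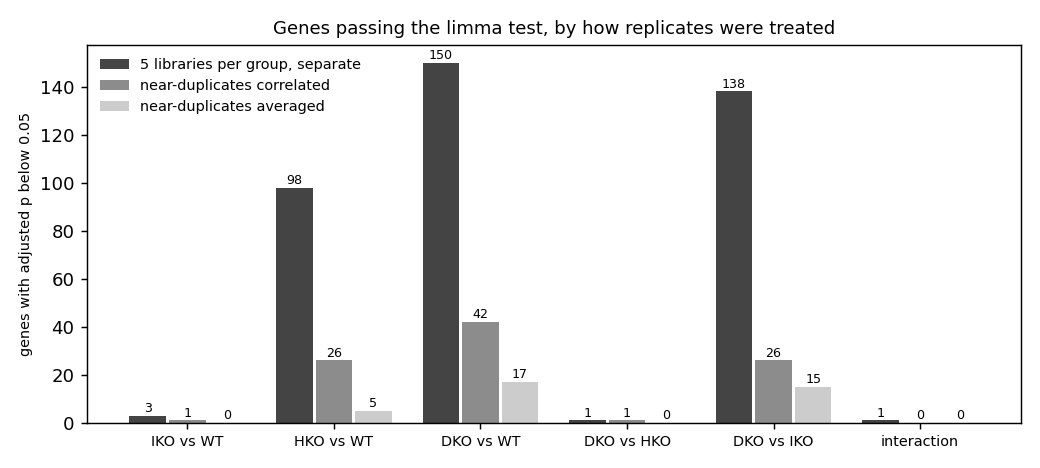
Number of genes at a limma adjusted p below 0.05 in the 6 comparisons, with dark bars for 5 separate libraries per group, mid-grey bars for close pairs treated as correlated and light bars for close pairs averaged. The counts for HKO against WT were 98, 26 and 5.

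Adding the loss of Foxo1 to the loss of Hnf4a, DKO against HKO, changed 1 gene past the threshold, Foxo1 itself (459 had an unadjusted p under 0.05). Averaging left 0 genes by limma (145 at an unadjusted p under 0.05) and the correlated fit 1. Of the 98 genes that differed in HKO against WT, 0 passed in the opposite direction and 0 in the same direction in DKO against HKO (limma, with 5 and 6 at an unadjusted p under 0.05). With array weights, where 947 genes passed in HKO against WT and 589 in DKO against HKO, 114 passed in opposite directions and 13 in the same direction. All other settings gave 0 opposite. The DKO minus HKO difference had the opposite sign in 53 and the same sign in 45. The median change in the direction of the HKO effect was 0.57 from WT to HKO and 0.58 from WT to DKO, and the further step from HKO to DKO was −0.01. The WT to HKO and HKO to DKO steps share HKO libraries, which alone pushes the later step to the opposite sign. With genes picked on part of the HKO libraries and the later step taken from the rest, in 10 splits, 20.8 to 45.5% of the 43 to 101 genes had the opposite sign (median 36.0%), and the median later step was 0.0279 to 0.226 in the direction of the HKO effect. In 8 of these splits a close pair was parted, so that HKO libraries on either side stayed alike. The other 2 gave 20.8 and 45.5%, with steps of 0.226 and 0.0362. In those 2, the picking and the later step used different library sets of HKO. This by itself can push the later step to the same sign. Neither kind of split is free of such a pull, so the splits do not settle whether Foxo1 loss offsets the loss of Hnf4a. In the same direction as in HKO against WT, 76 of the 98 passed in DKO against WT, which shares the WT libraries, and 52 in DKO against IKO, which shares no library. In 100 simulations of unchanged groups these shared counts had means of 1.65 and 0, with 100 and 0 the highest. A median of 0 genes passed in each of these comparisons there, so many draws had none to share. These means therefore do not tell how many genes lists of the real length would share by chance. The covariance of the 2 steps over all genes was −0.0124, against a mean of −0.0114 in 100 simulations of unchanged groups (−0.0246 to 0.00249).

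Lists that differed between DKO and HKO were cholesterol synthesis, higher with a median of 0.20 and 19 of 20 members above 0 (camera adjusted p = 2.32e-06, adjusted p = 0.383 with an estimated correlation), and acinar markers, lower with a median of −1.09 (9.59e-11, adjusted p = 0.592 with an estimated correlation). Within replicates 1 and 2, replicate 3 and replicates 4 and 5 the acinar median was −0.50, 1.73 and −3.13. Lactogen response genes, which follow prolactin signalling in beta cells, had a median of 0.19 with 8 of 8 measured members above 0 and 1 higher adjusted over the list alone (adjusted p = 0.0178, 0.245 with an estimated correlation). Glucose sensing and exocytosis (median 0.07, 0.0261, 0.748 with an estimated correlation) and endothelial markers (0.40, 0.0425, 0.706 with an estimated correlation) were called higher and oxidative phosphorylation lower (−0.05, 0.0143, 0.706 with an estimated correlation). A library set went the other way for glucose sensing (replicate 3, −0.04), endothelial markers (replicates 4 and 5, −0.11) and oxidative phosphorylation (replicates 4 and 5, 0.01). No member of these lists passed over all genes in limma. Leaving out 1 library ended the calls of lactogen response (HKO replicate 3, adjusted p up to 0.143) and glucose sensing (HKO replicates 4 or 5 or DKO replicates 1 or 3, up to 0.138). It also ended those of oxidative phosphorylation (HKO replicates 2 or 4 or DKO replicates 1 to 3, up to 0.180) and endothelial markers (IKO replicates 1, 3 or 4, HKO replicates 1 to 3 or DKO replicate 3, up to 0.735).

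The single knockouts shared 1 gene, Myo7a, higher in both (in HKO log2 1.09, SE 0.24, limma adjusted p = 0.0306), and 0 genes lower in both or opposite. Independent lists of these sizes would share 0.00353 genes higher in both. Simulated unchanged groups against the same WT libraries shared a mean of 0.2 genes in the same direction, and 1 or more in 7 of 100 draws (highest 8). A median of 0 genes passed there in either comparison, so many draws had none to share. With array weights 38 genes were shared in the same direction and 3 in opposite ones. The count was 2 without WT or IKO replicate 3 and 0 without WT replicates 1, 2, 4 or 5 or IKO replicates 4 or 5. The call of Myo7a in HKO was lost without any 1 of WT replicates 1, 2, 4 or 5 or HKO replicate 3 (adjusted p up to 0.1001). The covariance of the IKO and HKO log2 fold changes over all genes was 0.00746, against a simulated mean of 0.0105 (−0.00640 to 0.0293) from the shared WT libraries alone. With the WT libraries split between the comparisons in 20 ways the median covariance was 4.19e-05 (−0.0160 to 0.00521). Most of these ways parted a close WT pair, and the 4 that did not gave −0.0160 to −0.00186. In those 4, the comparisons drew on different library sets of WT, which by itself can pull the covariance below 0. Neither kind of split tells whether the knockouts acted alike or in opposite directions.

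The interaction asks whether the effect of losing Foxo1 depended on Hnf4a. Copz2, a subunit of the coatomer, a vesicle coat, was the 1 gene that passed (log2 −0.48, SE 0.07, limma adjusted p = 0.0274). It measured 32.7 ± 1.11 FPKM in WT, 38.5 ± 3.01 in IKO, 37.0 ± 1.34 in HKO and 31.0 ± 1.35 in DKO (n = 5). It passed in neither the averaged nor the correlated fit, both with 0 genes by limma (148 and 170 at an unadjusted p under 0.05), and was lost without WT replicates 1, 4 or 5, IKO replicates 3 to 5, HKO replicates 2 to 5 or DKO replicates 1 to 4 (adjusted p up to 0.0940), while 2 genes passed without WT replicate 3. Cholesterol synthesis genes showed the interaction as a list, with a median of 0.38 and 17 of 20 members above 0 (camera adjusted p = 5.51e-10, adjusted p = 0.245 with an estimated correlation). None passed over all genes in limma and 10 were higher adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, measured 15.4 ± 2.63 FPKM in WT, 12.9 ± 3.01 in IKO, 13.8 ± 1.33 in HKO and 17.1 ± 1.81 in DKO (log2 interaction 0.56). The set medians were 0.19, 0.27 and 0.50. Interferon response and MHC class I genes had a median of 0.49 (adjusted p = 2.92e-06, adjusted p = 0.706 with an estimated correlation), with set medians of −0.27, 1.10 and 0.83.

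Other lists called for the interaction were glycolysis (median −0.31, camera adjusted p = 0.000200, 0.592 with an estimated correlation), immune markers (0.51, 0.00511, 0.592 with an estimated correlation) and fatty acid and triglyceride synthesis (0.16, 0.0188, 0.706 with an estimated correlation, 2 higher adjusted over the list alone). Glucose sensing and exocytosis (0.11, 0.0253, 0.748 with an estimated correlation), acinar markers (−0.70, 0.0287, 0.774 with an estimated correlation) and endothelial markers (0.50, 0.0287, 0.706 with an estimated correlation) completed the 8. Within replicates 1 and 2, replicate 3 and replicates 4 and 5 the median was −0.70, 0.41 and −0.55 for glycolysis, −0.04, 2.09 and −2.60 for acinar markers and 0.58, 1.94 and −0.19 for immune markers. It was also opposite in replicate 3 for fatty acid synthesis (−0.09) and glucose sensing (−0.21), and in replicates 1 and 2 for endothelial markers (−0.00133). Leaving out 1 library ended the calls of immune markers (WT or HKO replicate 3, adjusted p up to 0.160), fatty acid and triglyceride synthesis (IKO replicates 4 or 5, HKO replicate 4 or DKO replicate 3, up to 0.0782) and glucose sensing (WT replicate 2, IKO or HKO replicates 4 or 5, up to 0.111). It also ended those of endothelial markers (WT replicates 4 or 5, IKO replicates 1 or 2, HKO replicates 1 to 3 or DKO replicate 3, up to 0.241) and acinar markers (WT replicates 4 or 5, IKO replicates 1 to 3, HKO replicates 4 or 5 or DKO replicates 1, 2, 4 or 5, up to 0.392). Over all comparisons, camera with the preset correlation called 43 of 150 tests, and 20 of these calls held with any 1 library left out. In 24 of the 43 a library set had a median of the opposite sign. Where that set was replicate 3, the median rested on 1 library per genotype, and these libraries did not deviate alike. With an estimated correlation camera called 0 (15 at an unadjusted p under 0.05, lowest adjusted p 0.245) and fry called 0 (18 at an unadjusted p under 0.05, lowest adjusted p 0.0759). The median, mean and test had the same sign in all 43, and differed in sign in 19 of the other tests.

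**Figure D4:**
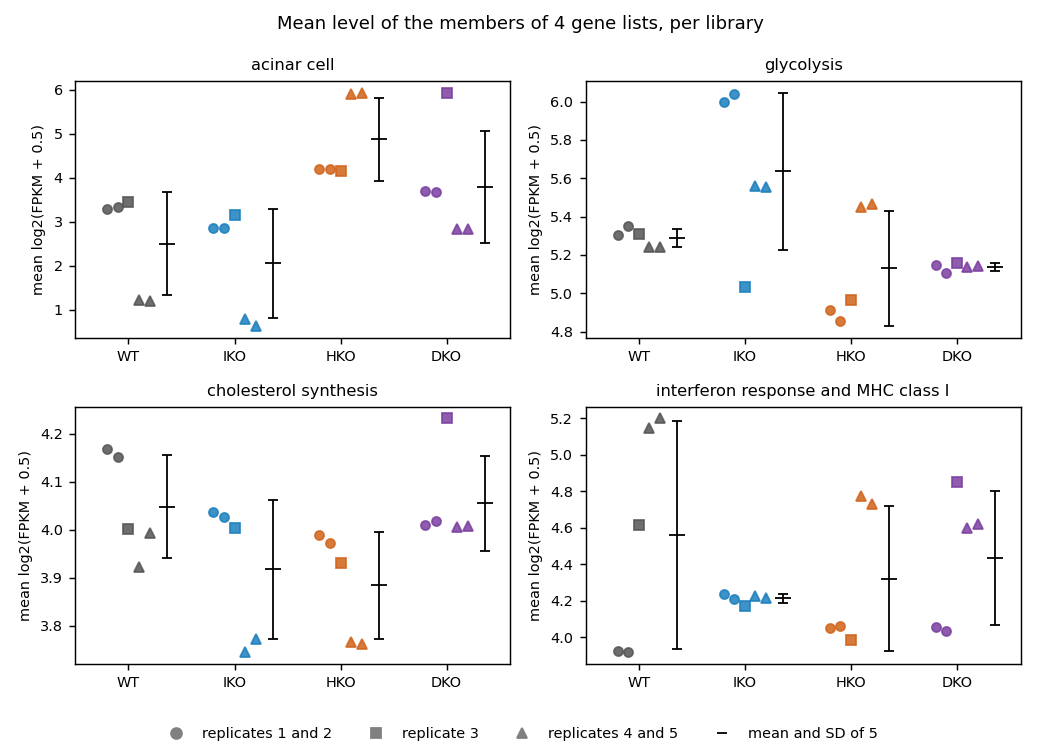
Mean log2(FPKM + 0.5) of the members of 4 gene lists in each of the 20 libraries by genotype, with circles for replicates 1 and 2, squares for replicate 3, triangles for replicates 4 and 5, and black bars for the mean ± SD of 5. The acinar mean was 2.5 in WT and 4.87 in HKO, and the glycolysis mean ranged from 5.03 to 6.04 in IKO and from 5.10 to 5.16 in DKO.

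Beta cell transcription factors, insulin production and granule genes, and dedifferentiation and progenitor genes showed no call as lists. Glucose sensing and exocytosis and the genes disallowed in beta cells had the calls given above. Beta cell transcription factors had medians of −0.06 (HKO against WT) to 0.06 (DKO against WT) over 16 members, and none passed in limma in any comparison. Mafa, an activator of insulin transcription, measured 135 ± 29.2 FPKM in WT, 115 ± 38.2 in IKO, 163 ± 52.0 in HKO and 170 ± 7.94 in DKO, and Nkx6-1 107 ± 17.8, 110 ± 16.3, 117 ± 22.1 and 120 ± 4.06. Insulin production and granule genes had medians of −0.03 to 0.02 over 18 members, with Nnat the 1 member that passed, lower in HKO and DKO (limma). Against WT its adjusted p with close pairs averaged and correlated was 0.103 and 0.0364 in HKO and 0.205 and 0.102 in DKO. Ins2 measured 243411 ± 32843 FPKM in WT, 239477 ± 20830 in IKO, 247888 ± 40189 in HKO and 236291 ± 36132 in DKO, differences smaller than these SDs. Dedifferentiation and progenitor genes had medians of −0.21 to 0.08 over 9 of 18 members, and Gpx2, a glutathione peroxidase, was the 1 that passed (HKO against WT log2 −0.50, limma adjusted p = 0.0247, DKO against WT −0.44, 0.0464). With close pairs correlated these were 0.102 and 0.406, and averaged 0.698 and 0.999877. The former was lost without WT replicates 2 to 5 or HKO replicates 1 to 3 (adjusted p up to 0.0770), and the latter without any 1 WT library, IKO replicate 1, HKO replicates 1, 2 or 5 or DKO replicates 1, 2, 4 or 5 (up to 0.132).

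Among markers of other cell types, alpha cell genes had medians of −0.05 to 0.15 over 9 of 15 members and delta, PP and epsilon cell genes −0.00 to 0.33 over 10 of 14. Npy was the 1 member of the latter that passed. Gcg, the glucagon gene, measured 726 ± 310 FPKM in WT, 520 ± 86.6 in IKO, 742 ± 203 in HKO and 900 ± 342 in DKO. Ductal cell genes had medians of 0.00 to 0.13 over 11 of 14 members, with Krt19 higher in DKO against WT. Of the stellate cell and fibroblast genes 1 was measured, Sparc, with log2 fold changes of −0.55 to 0.49. FoxO targets had medians of −0.01 to 0.09 over 22 members. Irs2, an insulin signalling adaptor, was lower in DKO than IKO (log2 −0.34, limma adjusted p = 0.0361), a call lost without any 1 of IKO replicates 1, 2, 4 or 5 or DKO replicates 1 to 4 (adjusted p up to 0.108) and in the correlated and averaged fits (0.808 and 0.999724). Fatty acid oxidation genes had medians of −0.05 to 0.01 over 18 members and cell cycle genes −0.06 to 0.17 over 11. The lowest camera adjusted p over the 10 lists without any call was 0.0527, for cell cycle genes in the interaction.

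The named genes lie across the genome (GRCm38). Anks4b is on chromosome 7 (120173858 to 120185586, plus strand), Sparcl1 on chromosome 5 (104079111 to 104113733, minus strand) and Elovl2 on chromosome 13 (41182381 to 41220405, minus strand). Tmprss4 is on chromosome 9 (45172726 to 45204092, minus strand), Dio1 on chromosome 4 (107291465 to 107307169, minus strand) and Vil1 on chromosome 1 (74409376 to 74435559, plus strand). Oat is on chromosome 7 (132557478 to 132576398, minus strand), Arhgap36 on the X chromosome (49463945 to 49500244, plus strand), Copz2 on chromosome 11 (96849870 to 96861203, plus strand) and Nnat on chromosome 2 (157560078 to 157562522, plus strand). All are annotated as protein-coding, and the values cover whole genes.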

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

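Apart from 2 tests, that of 1 shared factor in the acinar genes and that of the low-oxygen genes between HKO libraries, the tests in this part were chosen only after the result was seen.

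Of 220 groups of 5 libraries checked for 55 named genes, 21 (9.55%) held a library apart from the other 4, where chance gives about 1 in 20 for independent libraries. Of the 21, 20 were replicate 3, which follows in part from the close pairs, since each library of a pair has its partner near. The gap to the nearest library as a share of the group's range, against a critical value of 0.71, was 0.823 for Gatm, 0.895 for Fdps, 0.802 for Gpx2, 0.816 for Krt19, 0.917 for Ctrb1 and 0.884 for Cela2a, all highest in DKO replicate 3. In the same library Sparcl1 (0.862), Anxa10 (0.765) and Fos (0.754) were lowest. WT replicate 3 was highest for Fdps (0.785), Fos (0.786), Zfp36 (0.732) and Tpi1 (0.750) and lowest for Ttr (0.865) and Gcg (0.731), where it held 194 FPKM against 772 to 986 in the others. IKO replicate 3 was highest for Cldn11 (0.780) and Fos (0.7101). HKO replicate 3 was highest for Myo7a (0.966) and Hgfac (0.885) and lowest for Ins1 (0.838). DKO replicate 5 was highest for Nnat (0.782).

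The interaction passed for Copz2 (−0.48) with 5 libraries per group, but not with close pairs averaged (limma adjusted p = 0.999919) or correlated (0.673). Among the lists called by camera at the preset correlation, of which 0 were called with an estimated one (1 at an unadjusted p under 0.05), the median interaction was 0.11 for glucose sensing and exocytosis, −0.70 for acinar markers, 0.50 for endothelial markers, 0.51 for immune markers, −0.31 for glycolysis, 0.38 for cholesterol synthesis, 0.16 for fatty acid and triglyceride synthesis and 0.49 for interferon response and MHC class I. Entries without a gene name, which entered no comparison, took 0.201% of reads in HKO replicate 4 and 0.204% in HKO replicate 5, above the highest WT library.

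The number of genes passing was set against 100 splits of the same libraries into groups of 5, the real one included. As many genes passed in 4 splits for IKO against WT (real 3, highest other 1572), 2 for HKO against WT (98, 4423), 2 for DKO against WT (150, 2456), 3 for DKO against IKO (138, 732) and 3 for the interaction (1, 3572), each under 5 in 100. Since most splits part the close pairs that the real groups keep together, these shares do not exclude chance. Simulated unchanged groups that keep the pairs gave as many in 14, 3, 3, 4 and 16 of 100 draws. In the other simulation, with close pairs but genes drawn independently, a median of 145 genes passed for HKO against WT with nothing changed. For DKO against HKO 7 splits gave as many (1, 3383), and chance is not excluded. The highest splits for IKO, HKO and DKO against WT and for DKO against IKO set replicates 1 and 2 of both groups and 1 replicate 3 apart from the rest, and called several times more genes than genotype did, which points to a structure of the samples along the library sets. With close pairs averaged the genotype counts were 0, 5, 17 and 15. For the number of lists passing when adjusted over the 25 of a comparison alone, not over all 150 tests, 42 splits gave as many for IKO against WT (real 6, highest other 12), 32 for HKO against WT (9, 12), 94 for DKO against WT (4, 11), 75 for DKO against HKO (6, 14), 18 for DKO against IKO (8, 10) and 17 for the interaction (9, 13), so that chance is not excluded for any of them.

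Acinar transcripts stood higher in HKO and DKO libraries, most in HKO replicates 4 and 5 and DKO replicate 3, although sorting on the reporter should remove acinar cells. In HKO against WT the acinar median was 2.49. Other medians were 0.20 (delta, PP and epsilon), 0.03 (ductal), −0.05 (alpha), −0.22 (immune) and −0.45 (endothelial, 6 genes of low level whose call was not stable). A loss of beta cells that raises every other cell type alike is argued against for HKO by these values. It is left open for DKO replicate 3, where alpha (0.67), immune (0.57) and endothelial (1.63) medians over WT replicate 3 rose too. Each of these values sets 1 library against another. WT replicate 3 had the lowest alpha marker mean of the WT libraries (log2 3.37, others 3.69 to 3.93), and DKO replicate 3 stood at 4.00. RNA from acinar cells is a candidate explanation, and 97.7% of the variance of the 19 genes over the 20 libraries ran along 1 shared factor. Genes that vary together in any cell would give such a factor, so it does not tell where the RNA came from. Whether loss of Hnf4a brought the higher acinar level cannot be told, since the median within library sets was as low as 0.38 and ranged up to 4.82. The list mean differed in HKO against WT (exact p = 0.00794) but not past 0.05 in DKO against WT (exact p = 0.190). The permutation counts close pairs as separate libraries. Most of the HKO difference came from replicates 4 and 5, with set medians of 0.91, 0.78 and 4.82.

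Genes of the low-oxygen response, a list of 23 chosen after seeing the data with 22 measured, had a median of 0.69 in IKO against WT (21 of 22 above 0, exact p = 0.0476, adjusted p = 0.0794), of −0.20 in DKO against WT (3 of 22 above 0, exact p = 0.00794, adjusted p = 0.0397) and of −0.87 in DKO against IKO (exact p = 0.0476, adjusted p = 0.0794, 8 genes lower in limma), with Ldha at 4.57 ± 0.876 FPKM in WT and 23.0 ± 18.3 in IKO. In DKO against HKO the median was −0.11, with 0.09, 0.01 and −0.33 in replicates 1 and 2, replicate 3 and replicates 4 and 5. The last rests on HKO replicates 4 and 5, which stood high in these genes. A rise like the 1.20 of IKO against WT in replicates 1 and 2 was not seen without Hnf4a, but a smaller response to Foxo1 loss is not excluded. A difference in oxygen or handling between libraries may contribute, since the same genes differed in like proportion between HKO replicates 4 and 5 and HKO replicates 1 and 2 (r = 0.82, rho = 0.85 across 22 genes, which are not independent replicates, permutation p = 1e-05, the smallest 100000 resamples can give). Whether Foxo1 loss acts where Hnf4a is present cannot be told, since the median within library sets was 1.20, −0.20 and 0.60.

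Genes that passed with Hnf4a loss were more frequent near Hnf4a on chromosome 2. Within 50 Mb lay 17 of the 179 genes passing in HKO against WT or DKO against IKO, against 7.04 expected (odds ratio 2.62, Fisher's exact p = 0.000693). Alone, HKO against WT had 7 of 96 against 3.78 (Fisher's exact p = 0.105) and DKO against IKO 15 of 134 against 5.27 (Fisher's exact p = 0.000248). Among the 17 were Ahcy, Nnat and Gatm. With close pairs correlated the count was 3 of 36 against 1.42 (p = 0.167). Strain variants carried along with the floxed allele are a candidate explanation for part of these 17. Variants that act only on nearby genes are argued against as the cause of all calls by the 162 genes elsewhere (33 of 36 with close pairs correlated). Whether such variants act on distant genes was not tested. Eif3j1 measured 10.2 ± 1.13 RPM (reads scaled to depth) in WT and 6.06 ± 0.656 in HKO and its near-identical copy Eif3j2 4.75 ± 0.363 and 7.78 ± 1.35, while the log2 ratio of their sum was −0.11 (exact p = 0.262), which is consistent with reads assigned to one copy or the other. No test told a local effect of Hnf4a loss on its neighbours apart from such variants.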

How the results depend on the processing

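Averaging the close pairs, the set term, the correlated fit, voom and the 2 acinar settings were chosen after seeing the data, and the others were fixed in advance. No named gene, called list or targeted gene reversed its direction under the alternatives run. With equal medians the share of higher calls in IKO against WT went from 66.7 to 33.3%, and the median of all genes in DKO against WT from 0.0168 to −0.00683. This scaling moves all genes of a library alike, so the shift of that median follows by construction. Its sign changed in every comparison but HKO against WT. Of 309 values of counts under settings fixed in advance 242 stayed within 1.5 times and 67 did not, and of 57 added ones 32 and 25. Named genes kept their side of the threshold in 2259 of 2537 such and 316 of 510 added values, and list calls in 1056 of 1290 and 95 of 129. For the targeted genes this held in 166 of 180 such and 30 of 36 added values. The test of recovered reads by a count model was not run, since the unit is FPKM, and the stellate list has no gene at 2 FPKM. Unless said otherwise, the cause of a difference was not tested.

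Array weights raised the counts to 224 (IKO against WT), 947 (HKO against WT), 888 (DKO against WT), 589 (DKO against HKO), 958 (DKO against IKO) and 99 (interaction), with 114 opposite calls, 38 shared genes and a covariance of 0.0213. Averaging left 0, 5, 17, 0, 15 and 0 genes, in part by construction from fewer samples, and 0 shared, and with the set as a term 1, 9, 25, 17 (DKO against IKO) and 0 (interaction), 0 shared. The correlated fit left 1, 26, 42, 26 and 0, 0 shared. A fold of 1.5 left 48, 75, 70 and 0 by construction. Voom gave 1 for IKO against WT, 0 for the interaction and 0 shared. No filter gave 1 for IKO against WT, 3 for DKO against HKO and 0 shared, and the 2 FPKM filter 1 and 0 shared. Quantile normalization gave 6 and 2 shared. Scaling to equal medians gave 0 for the interaction. Only the groups compared gave 88 for DKO against IKO and 0 shared. A pseudocount of 1 and the acinar covariate each gave 0 shared. Without the acinar-high libraries the interaction had 0 and the shared genes were 2. Camera with an estimated correlation and fry each called 0 lists.

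Single replicate numbers did not pair the libraries one to one. The lowest correlation of same-numbered libraries was −0.386, for replicate 3 in HKO against WT. Best with their own number correlated 7, 3, 5, 2 and 4 of 10 libraries in the 5 comparisons of groups. A close partner can match as well, so these counts do not show that libraries were unpaired. Across genotypes, libraries numbered 1 or 2 correlated at 0.0810 to 0.480 and those numbered 4 or 5 at 0.285 to 0.499. The main fit had no term for this shared structure. With the replicate number as a block the counts were 1 (IKO against WT), 193 (HKO against WT), 263 (DKO against WT) and 291 (DKO against IKO), with 0 shared.

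With 1 library left out, the counts ranged from 1 to 29 (IKO against WT), 66 to 114 (HKO against WT), 101 to 180 (DKO against WT), 85 to 250 (DKO against IKO) and 0 to 2 (interaction), stayed at 1 for DKO against HKO and 0 for opposite calls, and ranged from 0 to 2 for shared genes, 34 to 49 for lists and 0.00601 to 0.0109 for the covariance. Foxo1 ranged from −2.27 to −2.01 in IKO against WT, −1.96 to −1.80 in DKO against WT and −1.85 to −1.62 in DKO against HKO. Hnf4a ranged from −0.56 to −0.42 in HKO against WT, −0.50 to −0.37 in DKO against WT and −0.48 to −0.32 in DKO against IKO. Its limma adjusted p there ran from 0.0198 to 0.179, 0.0321 to 0.273 and 0.0394 to 0.308.

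Averaging ended the calls of Foxo1 in IKO against WT (−2.07, adjusted p = 0.0778) and DKO against HKO (−1.73, 0.447). Hnf4a passed in HKO against WT with equal medians (−0.47, 0.0438), quantile normalization (−0.47, 0.0368), array weights (−0.38, 0.0110), the replicate block (−0.48, 0.0275), voom (−0.52, 0.0453) and the acinar covariate (−0.63, 0.0343). With close pairs averaged or correlated its adjusted p there was 0.999995 and 0.917. In DKO against WT the same settings gave −0.45, −0.46, −0.42, −0.43, −0.49 and −0.51, and in DKO against IKO array weights gave −0.55. With close pairs averaged or correlated Hnf4a passed in neither of these comparisons (adjusted p 0.999877 and 0.999875 in DKO against WT). Depth limits what can be seen at low FPKM, since 3 reads in a gene of 1 kb correspond to 0.0864 to 0.133 FPKM.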

Other observations

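All tests in this part were chosen after the result was seen.

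The apical brush border is the microvillus-bearing surface of absorptive epithelia. Of 18 of its genes, a list drawn up after Anks4b and Vil1 were seen to fall, 12 were measured, and 8 passed as lower in HKO against WT, 8 in DKO against WT and 7 in DKO against IKO, with 0 higher (limma). With close pairs correlated 4, 6 and 4 passed. The medians were −0.61, −0.66 and −0.57. Ush1c, a scaffold protein of microvillus tips, measured 29.6 ± 3.17 FPKM in WT, 29.9 ± 3.43 in IKO, 19.97 ± 1.08 in HKO and 19.5 ± 2.24 in DKO (n = 5). The aminopeptidase gene Anpep measured 14.0 ± 0.921, 12.8 ± 2.49, 7.38 ± 1.01 and 7.54 ± 1.52 FPKM, and the guanylate cyclase gene Gucy2c 10.6 ± 1.26, 11.3 ± 1.87, 6.18 ± 0.889 and 5.41 ± 0.229. In IKO against WT and DKO against HKO 0 passed in limma, with medians of −0.08 and −0.05. Since Anks4b and Vil1 are among the 12, the counts do not test whether such genes as a class were lower.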
